A study of Homo sapiens with 92 samples.

How the data were processed

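The data are RNA sequencing of human ovarian cancer tissue, flash frozen and extracted as total RNA per the labels' protocols, with 75 libraries labelled as before and 17 as after guadecitabine. Libraries were grouped by the treatment label. Title codes put the earlier libraries at cycle 1, day 1 and the later ones at cycle 2, day 8. Per the submitters' processing notes, CASAVA 1.8.2, Trimmomatic 0.32 and TopHat2 2.0.10 were used with the human build hg19. The read counter, its annotation, its use of strand and any handling of reads that map to several places are not given in the sources used here.

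The analysis used 1 table that the authors deposited, their DESeq2 comparison of cycle 2, day 8 against cycle 1, day 1 per its name and file header. Its version, covariates and the libraries that entered it are not given in the sources used here. The mean normalized count in the deposited table, a coverage-type signal averaged over libraries and scaled by size factors, is never negative and not whole. The authors gave a log2 fold change and its standard error on the log2 scale for each gene. The authors' Wald statistic, a score, equalled the ratio of those values to within 3.1e-14. Each p-value and adjusted p-value was also taken as the authors deposited it, and the adjusted values equalled a Benjamini-Hochberg adjustment over the genes with a mean count of at least 1.09 to within 5.5e-15. The table held 36708 genes by versioned Ensembl identifier, of which 161 had a mean count of 0, 36547 had a statistic and 23087 had an adjusted p-value. The fold changes looked moderated: the 2934 genes with a mean count under 0.1 had a median absolute log2 fold change of 0.41 and none above 1.72, and no standard error exceeded 1.46. The labels do not state such moderation, and folds of low genes are understated if it was applied.

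Values per library were not used here, so no count test, paired fit, replicate removal or regrouping of samples was run, and no depth per library, SD or n accompanies a value. The depth behind each gene is given by its mean count. Most tumour codes had 2 libraries, and p-values then measure in part a spread that may be technical. Gene symbols, gene types, chromosome membership, and transcript GC content and length came from GENCODE release 29 on GRCh38, a different build from that of the alignment, so no coordinates are printed. A symbol was found for 34740 identifiers (94.6%), and GC content and length for 22130 tested genes (95.9%), which covered 95.5% of called genes.

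A gene was called at a deposited adjusted p below 0.05. Before the data were examined, 44 gene lists with 929 members were fixed, 896 of which matched the table and 844 of which had an adjusted p-value. They cover the drug's targets (DNA methylation machinery, cancer-testis antigens, germline genes, silenced tumour suppressors, imprinted genes, viral sensing, type I and II interferon, class I and II presentation, checkpoints), cell types of the tissue and its surroundings, and general programmes. Each list was tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistics of all genes that had one, with a preset correlation between genes of 0.01, 2-sided, and Benjamini-Hochberg adjustment over the lists. Calls were also counted per list and tested for excess with a 2-sided Fisher's exact test against the other tested genes. They were also adjusted again over the list alone, that is over all its measured members. Each list median was set against 10000 random lists of the same size matched on mean count. For the most abundant genes, draws past the top of the count order were set to the most abundant gene. Matched ranges are therefore unreliable for lists with many such genes, above all the mitochondrial list. Chromosome X was compared with autosomes by Fisher's exact test. Intervals are 95% (1.96 standard errors, or Wilson for shares) and cover the stated errors only. Trends on GC content, length and mean count were fitted by lowess with a span of 0.3 and subtracted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used. The relation of XIST and Y-linked genes to treatment was not analysed here.

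Named genes followed a rule set before the data were examined, which took 156 genes: the 10 largest called changes in each direction and the 5 smallest p-values in each direction among genes with a symbol and a mean count of at least 10, the 3 members of each list with the smallest p-values, and 11 genes chosen for the drug and disease. Of those 11, 10 matched the table and the other was not analysed here. Some genes the rule takes are not reported here. Named genes outside the rule are said to be chosen after their values were seen, or are counted members of a list. In the report, this holds for the members named beyond the 3 of a list, such as S100A12, EGR1 and DKK1.

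Alternatives fixed beforehand were adjusted p thresholds of 0.01 and 0.10, a minimum change of 2-fold, other filters on mean count (none, 10, 100), the statistic divided by the square root of 2 or by the robust spread of all statistics (genomic control, 1.43), and re-centring on genes with a mean count of at least 100. For lists they were ranking by log2 fold change, preset correlations of 0.05 and 0.10, a background of mean count at least 10, and ranks. The trend subtractions and the removal of genes with a mean count of 1000 or more were added after the data were seen. The steps were tested on simulated data. With 200 changed among 23087 genes and the deposited standard errors, 2.5% of genes changed by 1 log2 unit, 41.0% of those changed by 2 and 83.5% of those changed by 3 were recovered. List tests recovered 97.5% of lists shifted by 1.5 in the statistic and called 0.455% of unshifted lists. The list simulation shuffled the statistics over genes, which removes any correlation between members. The share of false calls is therefore understated where members of a list are correlated.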

Results

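RNA sequencing was performed on frozen human ovarian cancer tissue collected before and after guadecitabine, a drug that is broken down to decitabine and blocks DNA methyltransferases. The patients had platinum-resistant disease, and the comparison asks how the tumour transcriptome on treatment differed from that before it. The labels described 92 libraries. The pre-treatment group held 75 libraries from 39 coded tumours (cycle 1, day 1) and the post-treatment group held 17 libraries from 9 coded tumours (cycle 2, day 8). All 9 codes of the post-treatment group also occurred before treatment. Most codes had 2 libraries (36 of 39 before and 8 of 9 after treatment). All values below come from the authors' deposited table of this comparison, which gives 1 mean normalized count, log2 fold change, standard error and p-value per gene, with no values per library. Depth per library is therefore unknown, and the mean normalized counts summed to 10198302. Throughout, "higher" and "lower" mean after against before treatment, and ± is the standard error in that table.

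In the post-treatment tumours, the neutrophil receptor genes FPR1, FPR2 and CXCR2 were among the 10 largest rises, while abundant transcripts fell, such as HSP90AA1, a cytosolic chaperone, and VEGFA, the angiogenic growth factor. FPR1, a receptor for bacterial formyl peptides, was 28.2-fold higher (log2 fold change 4.82 ± 0.63, DESeq2 adjusted p = 8.26e-11) in the authors' deposited table. HSP90AA1 was 54.5-fold lower there (-5.77 ± 0.66, DESeq2 adjusted p = 9.44e-14 in the authors' deposited table). Of 23087 genes with an adjusted p, 1082 passed 0.05 in the authors' deposited table (DESeq2), 278 higher and 804 lower. There were 4031 genes with an unadjusted p below 0.05. Changes of at least 4-fold were seen for 166 of the higher and 541 of the lower genes, and changes of at least 16-fold for 17 and 141. Across all tested genes 50.2% of log2 fold changes were positive (95% Wilson interval 49.5 to 50.8). That interval treats genes as independent, which they are not, so it is too narrow and does not cover the spread between tumours. Genes with a mean count of at least 100 had a median of -0.12. Re-centring on that median gave 381 higher and 643 lower genes, so that 37.2% of calls were higher against 25.7% as deposited. Subtracting the trend on mean count gave 33.3%, on length 23.6% and on GC content 19.6%. Because most tumours had 2 libraries, dividing the statistic by the square root of 2 is a stricter reading. It left 136 genes (16 higher and 120 lower), FPR1 and HSP90AA1 among them. Of the 76 called genes that the naming rule took, 26 stayed past the threshold. They were PLAGL1, C3, VEGFA, LDHA, FOS, SNRPD2 and the genes with the largest changes or smallest p-values, other than HCAR3 (adjusted p = 0.075), FLRT1 (0.07), CEACAM3 (0.171) and PADI4 (0.065). The other calls that the rule took ended, including those of ZFP36 (0.0839), IL1B (0.103), VSIR (0.109), AURKB (0.0931), CENPE (0.0645), CDH1 (0.14), ACTA2 (0.142), OAS2 (0.221) and TTN (0.283).

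**Figure D1:**
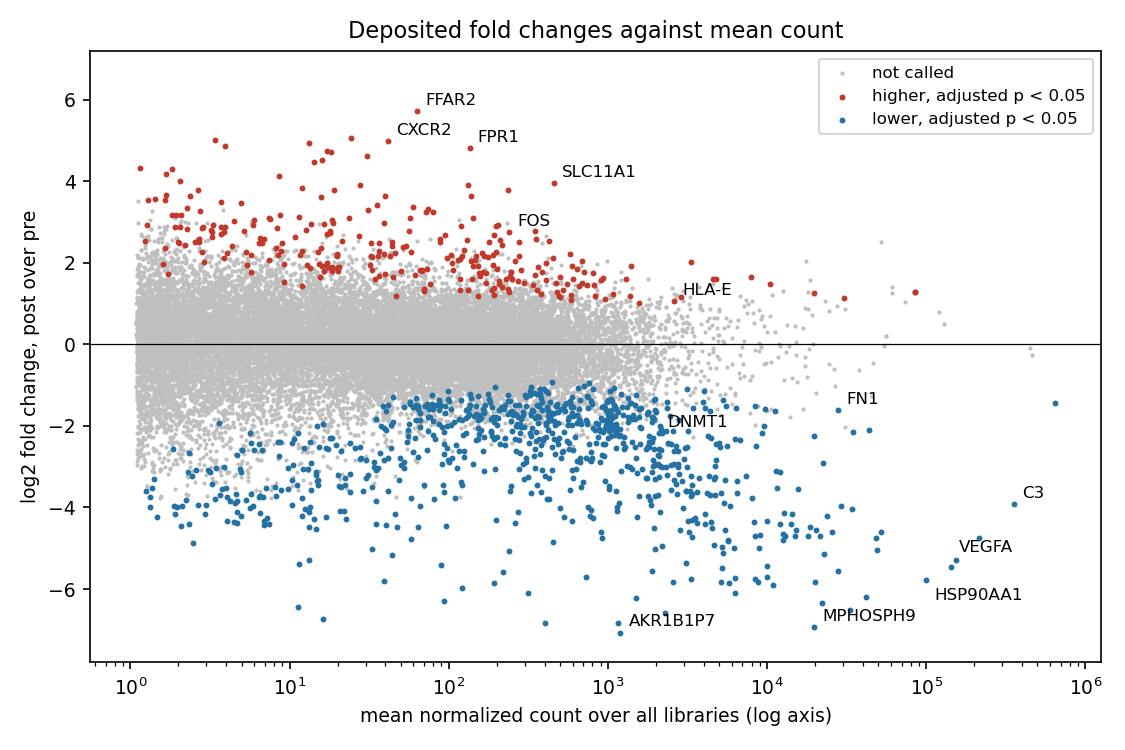
Log2 fold change after over before treatment against mean normalized count (log axis) for 23075 tested genes, 1 point per gene, from the authors' deposited table. Red and blue points passed adjusted p 0.05, and among genes with a mean count of 10000 or more 45 of 106 were lower and 5 higher.

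Neutrophil markers moved upward together. In the list of 17, every member had a positive log2 fold change and the median was 2.55. Of the members, 9 of the 16 with an adjusted p rose, none fell and 7 did not pass (11 rose when adjusted over the list alone). The chemokine receptor CXCR2 rose 31.8-fold (4.99 ± 0.81, DESeq2 adjusted p = 3.09e-07) and the formyl peptide receptor FPR2 rose 33.5-fold (5.06 ± 0.84, adjusted p = 4.87e-07) in the authors' deposited table. The calcium-binding protein gene S100A12 (4.17, mean count 1.68), PROK2 (3.79), CXCR1 (3.12) and the neutrophil-attracting chemokine CXCL8 (2.55) also rose in log2 units in the authors' deposited table. Outside the list, FFAR2, a receptor for short-chain fatty acids, showed the largest rise among genes with a mean count of at least 10 (52.4-fold, 5.71 ± 0.85, DESeq2 adjusted p = 1.08e-08 in the authors' deposited table). The hydroxycarboxylic acid receptor gene HCAR3 (26.9-fold), the cytidine deaminase APOBEC3A (26.5-fold), FLRT1 (24.5-fold), the granulocyte adhesion molecule CEACAM3 (22.8-fold), the histone-citrullinating enzyme PADI4 (22.1-fold) and the phagosomal metal transporter SLC11A1 (15.6-fold) followed in the authors' deposited table. LILRA6, a leukocyte receptor that shares near-identical sequence with LILRB3 and is uncertain for that reason, was 9.53-fold higher in the authors' deposited table. The neutrophil set had an adjusted p of 1.81e-22 (limma's cameraPR set test with a preset correlation of 0.01). It was 5.7e-10 at a preset correlation of 0.10 and 1.36e-07 with ranks. These p-values are over genes that can vary together and do not cover the spread between tumours. Without values per library, it is unknown whether all post-treatment tumours or only some had the rise. Lists of the same size matched on mean count had medians from -0.47 to 0.48. The list members S100A8 (1.23 ± 0.64) and S100A9 (1.48 ± 0.76), which neutrophils express very highly and which were chosen after their values were seen, had DESeq2 adjusted p of 0.303 and 0.292 in the authors' deposited table.

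Other immune lists lay above the rest of the genes with smaller values. B and plasma cell markers had a median log2 fold change of 1.15 with 18 of 20 positive, T cell markers 0.71 with 19 of 22, cytotoxic and natural killer markers 0.90 with 16 of 19, and lymph node stroma markers 1.19 with 9 of 10. No single member of these 4 lists passed the threshold, over all genes or adjusted over the list alone. Respectively 0, 1, 4 and 1 members had an unadjusted p below 0.05. The limma set tests had adjusted p of 0.00244, 0.00495, 0.00112 and 0.0107, which became 0.109, 0.147, 0.0965 and 0.109 at a preset correlation of 0.10. Their leading members in the authors' deposited table were CD22 (1.38 ± 0.78), CD3G (1.36 ± 0.65), GZMM (2.57 ± 0.88) and CCL19 (2.57 ± 0.97), with DESeq2 adjusted p of 0.347, 0.242, 0.0659 and 0.103. Macrophage and monocyte markers had a median of 0.44 (limma adjusted p = 0.0192, or 0.09 and 0.199 at preset correlations of 0.05 and 0.10). Among 21 members, FCN1 (5.65-fold) and TYROBP (3.26-fold) rose. Adjusted over the list alone, 3 rose and 2 fell. Subtracting the trend on GC content ended the call of TYROBP (adjusted p = 0.143) and of the macrophage list (limma adjusted p = 0.0948), and subtracting the length trend also ended the list's call (0.0847). Mast cell markers had a median of 0.65 (limma adjusted p = 0.0477) and 0 of 9 passed (3 members with an unadjusted p below 0.05), with TPSAB1 at 2.06 ± 0.80 in the authors' deposited table. The mast cell list passed under 3 of 10 settings of the set test, and its limma adjusted p was 0.101 at a preset correlation of 0.05. Dendritic cell (median 0.34, limma adjusted p = 0.609), endothelial (0.22, 0.995) and erythroid markers (0.25, 0.291) had no call over all genes (1, 3 and 1 with an unadjusted p below 0.05), and 1 erythroid gene was higher when adjusted over the list alone. For the endothelial list the median was positive and the mean statistic negative (-0.07).

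Immediate early genes, which answer growth factors and stress within minutes, included 5 that rose, 1 that fell and 17 that did not pass (6 and 2 adjusted over the list alone; median 0.70, limma adjusted p = 2.44e-04, or 0.0733 at a preset correlation of 0.10). The transcription factor FOS rose 6.77-fold (2.76 ± 0.52, DESeq2 adjusted p = 2.26e-05), the mRNA decay factor ZFP36 rose 6.85-fold (2.78 ± 0.58, 1.84e-04) and the phosphatase DUSP1 rose 5.72-fold (2.52 ± 0.58, 0.00118) in the authors' deposited table. EGR1 (2.11) and JUNB (1.66) rose and the heat shock gene HSPA1B (-1.74) fell in the same log2 units of the authors' deposited table. Among 23 chemokines and cytokines with an adjusted p (median 0.87, limma adjusted p = 0.00621, or 0.0577 and 0.164 at preset correlations of 0.05 and 0.10), IL1B rose 9.97-fold, CXCL1 rose 7.75-fold and CCL8 fell 7.18-fold in the authors' deposited table, with the same count adjusted over the list alone. Of 20 checkpoint genes, VSIR, which encodes the inhibitory ligand VISTA, rose 5.94-fold in the authors' deposited table and 19 did not pass, with the same count adjusted over the list alone. The checkpoint list median was 0.50 (limma adjusted p = 0.0663). CD274, the gene for PD-L1, was at 2.07-fold with a standard error of 0.70 in log2 units (DESeq2 adjusted p = 0.451) in the authors' deposited table. In the complement list C5AR1 (5.29-fold) and CFP (5.66-fold) rose and C3 fell 15-fold in the authors' deposited table. The other 16 of 19 did not pass, and 2 rose and 2 fell adjusted over the list alone. The complement median was positive (0.07) and its mean statistic negative (-0.09, limma adjusted p = 0.972).

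Many of the lower genes were among the most abundant in the table. Of 1025 genes with a mean count of 1000 or more, 280 were lower and 16 higher. The share of lower genes climbed from 1.11% of 6841 genes under a mean count of 10 to 25.6% of 919 genes from 1000 to 10000 and 42.5% of 106 genes above. The mean count is averaged over libraries, most of which were labelled pre-treatment. High counts before treatment therefore raise both a gene's mean count and its fall, so the 2 are not independent. Median standard errors were 0.82 under a count of 10, 0.45 from 100 to 1000 and 0.60 at 10000 or more, so falls were harder to call at low counts. The lower genes together held 32.6% of all mean counts against 2.93% for the higher genes. MPHOSPH9 (mean count 19632) was 122-fold lower, the actin-associated LIM protein gene PDLIM3 (33327) 91.6-fold, ZNF839 (22294) 80.5-fold, the cyclophilin-like PPIL4 (6284) 68.1-fold and VEGFA (142386) 44.1-fold in the authors' deposited table. PRPH2, a photoreceptor disc protein, was 96.4-fold lower at a mean count of 2284 and the testis kinesin KIF2B was 77.9-fold lower at 93.5 in the authors' deposited table. OCA2, a melanosomal transporter chosen after its value was seen, was 54-fold lower at a mean count of 8365 in the authors' deposited table. FAM205C (106-fold) and the unnamed antisense gene AC103843.1 (87.2-fold) also fell in the authors' deposited table, and counting by strand was not stated. Several falls concern sequences that share reads with a copy or a host gene and are uncertain. AKR1B1P7 (134-fold), AKR1B1P1 (114-fold) and REXO1L1P (114-fold) were lower in the authors' deposited table and are processed pseudogenes by their GENCODE gene type. AKR1B1 itself, chosen after its value was seen, was at 0.22 ± 0.40 (DESeq2 adjusted p = 0.834) in the authors' deposited table. SNORA68, a small nucleolar RNA gene, was 35.2-fold lower in the authors' deposited table, and such genes lie within longer transcripts whose reads they can share. Without the genes of mean count 1000 or more, 673 genes passed (225 higher and 448 lower).

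Stromal, muscle and hypoxia lists lay below the rest of the genes. Of 20 fibroblast markers 7 fell and 13 did not pass (11 fell adjusted over the list alone; median -1.27, limma adjusted p = 7.35e-11). Among them were the contractile genes ACTA2 (4.43-fold, -2.15 ± 0.47) and TAGLN (3.31-fold, -1.73 ± 0.40) and the microfibril gene FBN1 (3.39-fold, -1.76 ± 0.46) in the authors' deposited table. Smooth muscle contractile genes had a median of -0.97 with 0 of 12 positive (limma adjusted p = 4.51e-06). The 2 that fell were ACTA2 and TAGLN, and 6 fell adjusted over the list alone. SYNM of the same list was at -1.59 ± 0.58 (DESeq2 adjusted p = 0.0906) in the authors' deposited table. Skeletal muscle genes had a median of -2.32 (limma adjusted p = 9.09e-07). Of 16 members 4 fell, or 6 adjusted over the list alone, including the giant sarcomere proteins TTN (11.7-fold) and NEB (10.8-fold) and the myosin MYH7 (8.15-fold) in the authors' deposited table. In the hypoxia and glycolysis list 6 of 18 fell, with VEGFA, the lactate dehydrogenase LDHA (4.12-fold) and the histone demethylase KDM3A (8.03-fold) leading in the authors' deposited table. The hypoxia list had a median of -0.85 (limma adjusted p = 9.09e-07), and 2 rose and 7 fell adjusted over the list alone. Of the epithelial-mesenchymal transition genes, FN1 (3.08-fold) and AXL (2.58-fold) fell in the authors' deposited table, and 4 of 17 measured members fell adjusted over the list alone. Their list median was -0.44 (limma adjusted p = 0.0108). This median lay inside the range of matched lists (-0.68 to 0.34, 14.3rd percentile), and the list passed under 5 of 11 settings of the set test, with a largest adjusted p of 0.206. Adipocyte markers had a median of -1.11 (limma adjusted p = 0.0199), with the fatty acid carrier FABP4 7.08-fold lower in the authors' deposited table, the only 1 of 16 to pass by either adjustment. The adipocyte list passed under 6 of 11 settings, and its limma adjusted p was 0.332 on a background of mean count at least 10, 0.0847 with the length trend subtracted and 0.0501 with the mean-count trend subtracted. Leaving out genes of mean count 1000 or more, a choice made after the data were seen, ended the calls of the hypoxia list (limma adjusted p = 0.757) and the fibroblast list (0.0619), which kept 9 and 8 members.

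Cell division and DNA repair genes lay lower as groups, with 7 of 34 and 7 of 39 log2 fold changes positive, while few single genes passed. Of 34 proliferation genes, the mitotic kinase AURKB (12.9-fold), the centromere motor CENPE (12.2-fold) and the replication helicase subunit MCM6 (7.14-fold) fell in the authors' deposited table. The other 31 did not pass (4 fell adjusted over the list alone; median -0.50, limma adjusted p = 2.70e-05, or 0.0733 at a preset correlation of 0.10). MKI67 was at -1.34 ± 0.48 with a DESeq2 adjusted p of 0.0829 in the authors' deposited table. AURKB had a mean count of 4357, and 25.6% of all genes with a mean count from 1000 to 10000 fell. Of 39 DNA repair genes, FANCD2 (6.13-fold) and RAD50 (2.32-fold) fell in the authors' deposited table, and 3 fell adjusted over the list alone (median -0.38, limma adjusted p = 2.02e-04, or 0.109 at that correlation), and the RAD50 call ended with the GC trend subtracted (adjusted p = 0.0654). Core spliceosome genes included falls of the Sm protein genes SNRPD2 (5.75-fold), SNRPG (3.31-fold) and SNRPD3 (2.21-fold) in the authors' deposited table, 3 of 22 over all genes and 6 adjusted over the list alone. Their list median of -0.21 (limma adjusted p = 0.00563) lay at the 46.8th percentile of lists matched on mean count. Mitochondrially encoded genes had a median of -0.48 (limma adjusted p = 0.00320). The call ended with the mean-count trend (limma adjusted p = 0.825) or the GC trend (0.0942) subtracted. Matched lists put this median at the 92.2nd percentile but cannot judge it. The members are so abundant that draws often fell on the most abundant gene. The matched median (-1.43) equalled the log2 fold change of MT-RNR1, itself a member. MT-ND3 (8.63-fold) and the ribosomal MT-RNR1 (2.70-fold) fell in the authors' deposited table, 3 of 15 adjusted over the list alone.

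The drug's target DNMT1 fell, as did 25.6% of genes in its range of mean counts (1000 to 10000). No list of genes that methylation can silence passed the set test upward, though not all their members were silent in this tissue. DNMT1, the maintenance DNA methyltransferase, fell 4.51-fold (-2.17 ± 0.62, DESeq2 adjusted p = 0.0168) in the authors' deposited table, whereas DNMT3A (0.09 ± 0.59, 0.960) and DNMT3B (-0.33 ± 0.54, 0.810) did not pass. DNMT1 was the only call by either adjustment among 21 measured genes of the DNA methylation machinery, 20 with an adjusted p (median 0.07 and mean statistic -0.39, limma adjusted p = 0.392). HELLS (-1.28 ± 0.47, DESeq2 adjusted p = 0.0917) and TET3 (1.04 ± 0.42, 0.133) came next in the authors' deposited table. Dividing the statistic by the square root of 2 ended the DNMT1 call (adjusted p = 0.496). Cancer-testis antigens are normally kept silent outside the germline by promoter methylation. Of 35 fixed members only 24 were measured, so the others were not tested. The list had 0 calls by either adjustment, and 10 measured members had an adjusted p. An unadjusted p below 0.05 was found for 1 measured member, and the median was -0.52 (limma adjusted p = 0.40). MAGEC1 was at -3.30 ± 1.21 (DESeq2 adjusted p = 0.0891), CTCFL at -0.92 ± 0.75 (0.557) and MAGEA1 at -1.81 ± 1.37 (unadjusted p = 0.188) in the authors' deposited table. MAGEA3, with a mean count of 0.146, was at 1.03 ± 1.45 (unadjusted p = 0.476) in the authors' deposited table, so that a change was not detectable at this count. The handling of reads that map to several places is not given, so members with close copies may be undercounted. Germline genes silenced by methylation had 0 calls by either adjustment among 23 measured members, 16 with an adjusted p, and 1 unadjusted p below 0.05 (median -0.21, limma adjusted p = 0.879). TEX101 was at 1.34 ± 0.48 (DESeq2 adjusted p = 0.0827), TDRD9 at 1.39 ± 0.84 (0.388) and TDRD1 at -1.66 ± 1.11 (0.452) in the authors' deposited table. Tumour suppressors known to be silenced by methylation in cancer had 5 of 31 falls and no rise (7 falls adjusted over the list alone; median -0.30, limma adjusted p = 0.00870). The 5 were PLAGL1 (24.4-fold), the adhesion molecule CDH1 (7.06-fold), TIMP3 (2.95-fold), DKK1 (-3.58 in log2 units) and SPARC (-1.57) in the authors' deposited table. PLAGL1, CDH1, TIMP3 and SPARC had mean counts of 3228, 3021, 1608 and 9668. They were thus expressed in this tissue, in the range of mean counts where 25.6% of genes fell. The silenced tumour suppressor list passed under 5 of 11 settings of the set test. Its call ended without genes of mean count 1000 or more (limma adjusted p = 0.330) and with ranks (0.126). It also ended with the length trend (0.0847) or the mean-count trend (0.0746) subtracted. RASSF1 (0.21 ± 0.43, DESeq2 adjusted p = 0.856) did not pass in the authors' deposited table.

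No set test of interferon, viral sensing or antigen presentation genes, which this drug class is often asked about, passed upward. Type I interferon response genes had a median of -0.68 with 9 of 35 positive (limma adjusted p = 8.88e-04, or 0.131 at a preset correlation of 0.10). The antiviral enzyme gene OAS2 fell 8.59-fold (-3.10 ± 0.74, DESeq2 adjusted p = 0.00199), IFI6 fell 5.80-fold (-2.54 ± 0.66, 0.00621) and the signalling factor STAT2 fell 3.01-fold (-1.59 ± 0.48, 0.0266) in the authors' deposited table. The other 32 did not pass (1 rose and 4 fell adjusted over the list alone). In the interferon-gamma list WARS1 fell 3.18-fold in the authors' deposited table, 1 of 17 by either adjustment (median -0.29, limma adjusted p = 0.336), and ICAM1 was at -1.74 ± 0.65 (DESeq2 adjusted p = 0.101). OAS2, IFI6, STAT2 and WARS1 had mean counts of 1207, 3050, 1569 and 1778. From 1000 to 10000, 25.6% of all genes fell, so these falls are not particular to interferon genes. Without genes of mean count 1000 or more, the type I list still passed downward (limma adjusted p = 0.0245). Viral sensing genes had 0 calls by either adjustment among 23 measured members, 18 with an adjusted p, and 2 unadjusted p below 0.05 (median 0.24, limma adjusted p = 0.493). RIGI was at -0.96 ± 0.45 and CGAS at 1.29 ± 0.62 in the authors' deposited table. Class I presentation genes had a median of 0.43 (limma adjusted p = 0.291), which lay above the range of lists matched on mean count (-0.86 to 0.20, 99.9th percentile). Among them were a 2.09-fold rise of HLA-E and a 2.11-fold fall of PDIA3 in the authors' deposited table, with the same count adjusted over the list alone. Subtracting the trend on GC content ended both calls, to adjusted p of 0.0973 for HLA-E and 0.0592 for PDIA3. Class II presentation genes had 0 of 15 calls by either adjustment and 1 unadjusted p below 0.05 (median 0.06, limma adjusted p = 0.588), with HLA-DQB1 at -1.54 ± 0.70 in the authors' deposited table.

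**Figure D2:**
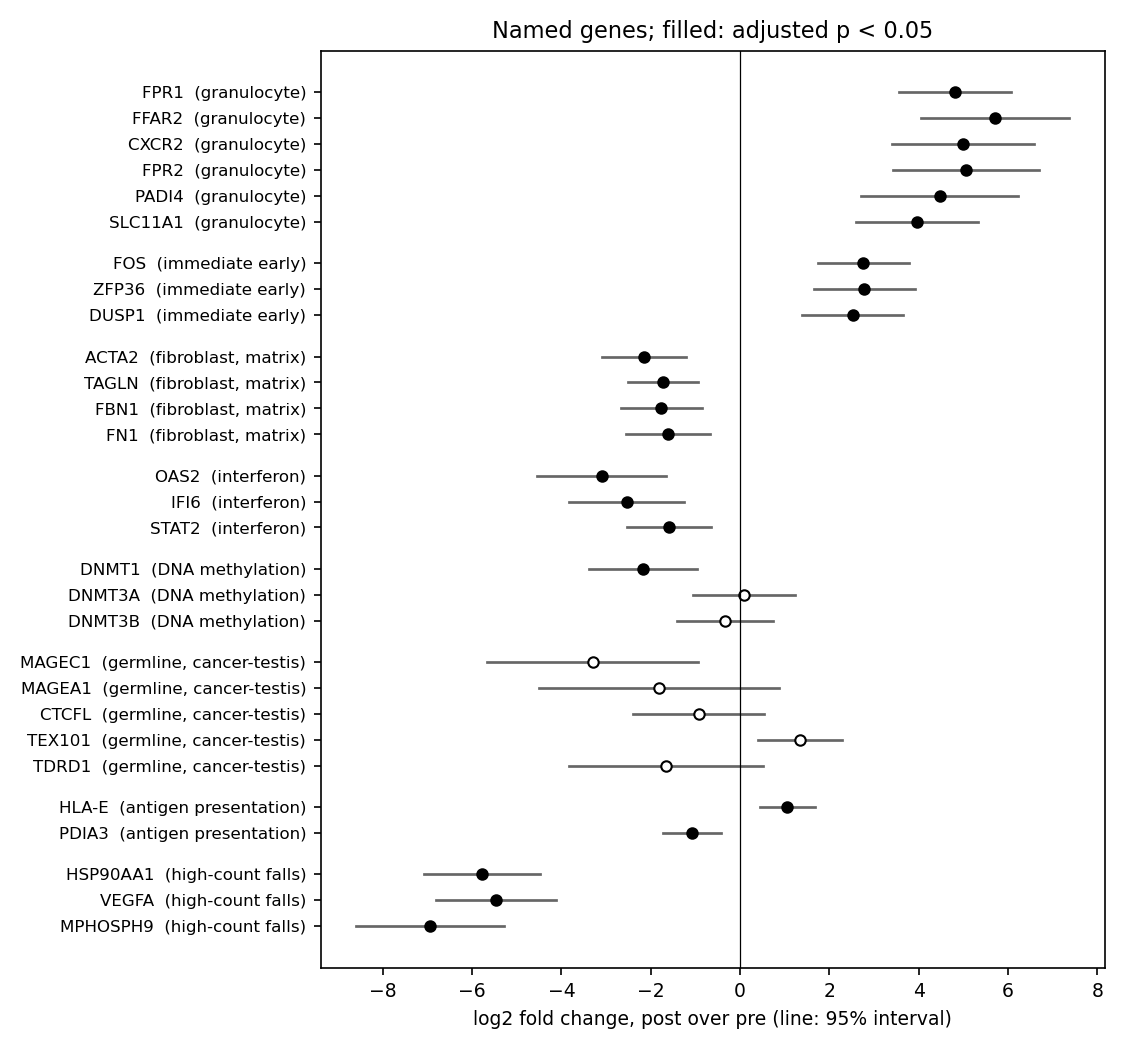
Log2 fold change after over before treatment for named genes by group, from the authors' deposited table. Lines are 95% intervals from the standard errors and filled points passed adjusted p 0.05, which DNMT1 (-2.17) did and all 5 germline and cancer-testis genes shown did not.

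Genes tied to platinum handling and to the tumour epithelium changed singly. The copper and platinum exporter gene ATP7B fell 9.43-fold (-3.24 ± 0.81, DESeq2 adjusted p = 0.00375) and the copper transporter SLC31A2 rose 4.38-fold (2.13 ± 0.56, 0.00778) in the authors' deposited table. The other 22 of 24 platinum transport and detoxification genes with an adjusted p did not pass. Adjusted over the list alone, 1 of 25 measured members rose and 1 fell (median -0.11, limma adjusted p = 0.291). CDA, the cytidine deaminase that inactivates decitabine, was at 0.51 ± 0.85 (DESeq2 adjusted p = 0.810) in the authors' deposited table. Among p53 targets BTG2 rose 2.82-fold and TRIAP1 fell 3.68-fold in the authors' deposited table. The other 25 of 27 did not pass (2 rose and 1 fell adjusted over the list alone; limma adjusted p = 0.909). The p53 median (-0.03) and mean statistic (-0.02) were negative while the set test pointed up. Ovarian epithelial markers had a positive median (0.16) and a negative mean statistic (-0.42, limma adjusted p = 0.321), and CDH1 and ELF3 (2.87-fold) were the 2 of 24 that fell in the authors' deposited table, with 1 rise and 2 falls adjusted over the list alone. WFDC2, the gene for the serum marker HE4, was at 1.61 ± 0.58 (DESeq2 adjusted p = 0.0860) and MUC16, the gene for CA-125, at -1.59 ± 0.63 (0.127) in the authors' deposited table. Dividing the statistic by the square root of 2 ended the ATP7B call (adjusted p = 0.286). ATP7B had a mean count of 4292, and 25.6% of all genes with a mean count from 1000 to 10000 fell.

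The remaining lists had few calls and no passing set test. The activin subunit INHBA fell 3.78-fold among 22 WNT and TGF-beta genes (median 0.35, limma adjusted p = 0.274), PLAGL1 was the only call among 20 imprinted genes (-0.09, 0.308) and CDH17 fell 18-fold among 5 intestinal markers (-0.39, 0.590) in the authors' deposited table, each with the same count adjusted over the list alone. The INHBA call ended with the GC trend subtracted (adjusted p = 0.068). RPS19 fell 2.93-fold in the authors' deposited table as the only 1 of 38 cytoplasmic ribosomal protein genes, with 3 rises and 2 falls adjusted over the list alone (median 0.19, limma adjusted p = 0.0798). Stemness genes (median 0.44, limma adjusted p = 0.879), replication histones (0.52, 0.263), hepatocyte markers (-0.61, 0.291) and mesothelial markers (-0.21, 0.879) had 0 calls over all genes, and 2, 0, 0 and 3 members with an unadjusted p below 0.05. Adjusted over the list alone, 1 mesothelial gene was higher and 1 lower, and the other 3 of these lists had 0 calls. On chromosome X 6 of 713 tested genes were higher (0.842%) against 254 of 21377 on autosomes (1.19%), and 21 were lower (2.95%) against 745 (3.49%), and neither difference passed (2-sided Fisher's exact tests, both adjusted p = 0.531). In all, 21 of the 44 fixed lists passed the limma set test, 9 upward and 12 downward. Of these 5 passed Fisher's exact test of called against uncalled genes, namely the neutrophil, fibroblast, hypoxia, immediate early and skeletal muscle lists. Re-centring, which adds 0.12 to every log2 fold change, turned the medians of the p53, imprinted and platinum lists positive, since these lay closer to 0 than that shift. The medians of 6 lists that passed the set test lay inside the range of lists matched on mean count, namely the hypoxia, silenced tumour suppressor, mast cell, epithelial-mesenchymal transition, mitochondrial and spliceosome lists. The range of the mitochondrial list cannot judge its median, since its draws often fell on the same gene. Another 6 lists did not pass although their medians lay outside the range of their matched lists. These were cancer-testis antigens below it, and class I presentation, WNT and TGF-beta, checkpoint, ribosomal protein and histone genes above it. No correlation between genes could be estimated without values per library. With a preset correlation of 0.10 the 5 lists that still passed were the neutrophil, skeletal muscle, smooth muscle, fibroblast and hypoxia lists.

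**Figure D3:**
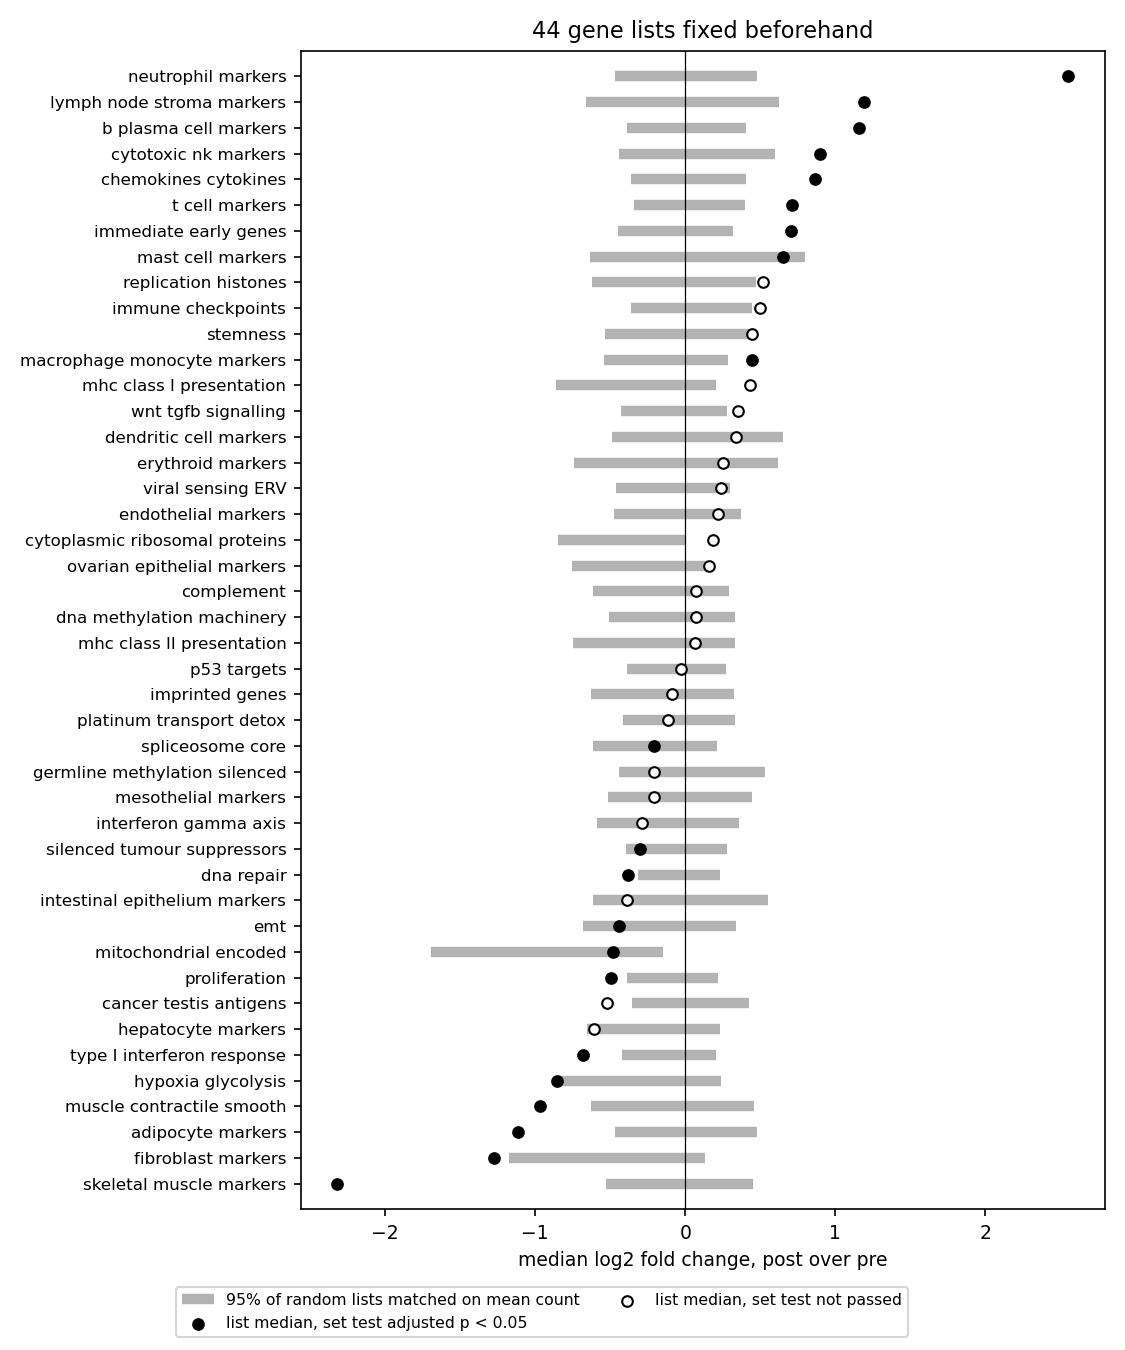
Median log2 fold change after over before treatment of the 44 fixed gene lists (points; filled where the limma set test had adjusted p below 0.05), with grey bars for the middle 95% of 10000 random lists matched on mean count. The bar of the mitochondrial list is not informative, because its draws often fell on the most abundant gene. Neutrophil markers lie highest (2.55) and skeletal muscle markers lowest (-2.32).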

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

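The GC, length and mean-count trends, the removal of genes with a mean count of 1000 or more, the list counts by Fisher's exact test under other settings, and the overall shift at higher counts were chosen after seeing the data. The number of called genes stayed within 1.5 times of 1082 with a 2-fold minimum (1080), other filters on mean count (871 without a filter, 1044 at 10, 940 at 100), re-centring (1024), and subtraction of the GC (1011), length (973) or mean-count trend (950). It moved to 477 (83 higher, 394 lower) at a threshold of 0.01, 1748 (539 higher, 1209 lower) at 0.10, 136 (16 higher, 120 lower) with the statistic divided by the square root of 2, 134 (16 higher, 118 lower) with genomic control, and 673 (448 lower) without genes of mean count 1000 or more, where fewer genes were tested. Of the 1011, 846 were among the 1082. The share of positive log2 fold changes, 50.2% of tested genes, was 47.5% at a mean count of at least 10 and 43.9% at 100 or more. The cause was not tested.

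Of the 44 lists, 21 passed as first tested and 5 at a preset correlation of 0.10. Between 14 and 22 passed under the other 9 settings, no list that passed changed direction under the settings able to change one (all but the preset correlations), and the neutrophil, skeletal muscle and smooth muscle lists passed under all 11. The least stable were the mast cell list, which passed under 3 of 10, and the epithelial-mesenchymal transition, silenced tumour suppressor and spliceosome lists, under 5 of 11 each, followed by the adipocyte and macrophage lists (6 of 11) and the mitochondrial list (6 of 10). By Fisher's exact test 1 list passed both with the square root of 2 and with genomic control, against 5 as deposited. Of 76 named genes that were called, 72 stayed called without a filter on mean count, 71 without the GC trend (ICAM1 was gained, and none changed direction), and 26 under each stricter statistic, which cannot change a direction. No paired analysis was possible because the deposited table gives 1 value per gene over all libraries. For the same reason no library was left out, no other split of the samples was drawn, and alternatives on values per library, listed beforehand, were not run. In simulation with 200 changed genes, a change of 1 log2 unit was found in 2.5% of genes. More genes were called in the data, which makes the threshold on the unadjusted p less strict, so this rate may be too low. Still, 1080 of the 1082 called genes changed at least 2-fold, so few changes of less than 1 log2 unit were called.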

Other observations

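The gene families below, and the single genes named outside the rule, were chosen after their values were seen, so families are described by values with no test. Also chosen after the results were seen were the 3 tests of the neutrophil pattern, while the 3 tests of the high-count pattern were set before their results. Leukocyte immunoglobulin-like receptors, which set activation thresholds on myeloid cells, had a median log2 fold change of 1.45 over 10 genes, with 4 higher and 1 lower. LILRB3 was 9.57-fold and LILRB2 6.44-fold higher in the authors' deposited table, though near-identical members share reads. Genes of the interleukin-1 and inflammasome system had a median of 0.83, and 4 of 18 rose and none fell. IL1RN, the interleukin-1 receptor antagonist, rose 10.3-fold (3.37 ± 0.65) and the sensor NLRP1 rose 4.45-fold (2.16 ± 0.45) in the authors' deposited table. Further single myeloid genes rose in the authors' deposited table, among them G0S2 (13.7-fold), the cytokine OSM (12.4-fold), TREM1 (7.88-fold), the transcription factor SPI1 (6.39-fold) and the integrin ITGAX (4.61-fold). Immunoglobulin genes had a median of 0.82 with 81 of 105 positive and 1 call, which was lower. IGHG1 was at 2.51 ± 0.85 (DESeq2 adjusted p = 0.0595) in the authors' deposited table.

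Families of small RNA genes had medians of different sign. In the imprinted SNORD113 and SNORD114 cluster, 22 of 24 tested genes were negative, 4 fell and none rose (median -1.40). SNORD114-26 fell 20-fold (-4.33 ± 0.72) and SNORD114-21 fell 16.2-fold (-4.01 ± 0.67) in the authors' deposited table, while MEG8 of the same region was at -0.01 ± 0.56 (DESeq2 adjusted p = 0.998) and MEG3 at -0.91 ± 0.45 (0.261). Other small nucleolar RNA genes had a median of 0.71 with 13 higher and 7 lower of 273. All genes of the small nuclear RNA type in GENCODE had a median of 0.97, with 9 higher and 1 lower of 192, and copies among them can share reads. With the length trend subtracted, the mean statistic of the other small nucleolar RNA genes was -0.00216. Processed pseudogenes had 43 lower and 4 higher of 734, and zinc finger genes 15 lower and 0 higher of 462. HBB, the beta globin gene, was at 0.08 ± 0.65 and IGF2, with a mean count of 465649, at -0.25 ± 0.68 in the authors' deposited table.

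High-count genes were lower after treatment, in a pattern that includes OCA2, CHGB and CAPN3 (54-fold, 74.8-fold and 56.9-fold lower in the authors' deposited table). Across genes, log2 fold change had a Spearman correlation of 0.27 with transcript GC content and -0.17 with length, and genes are not independent replicates. Subtracting the GC trend left the median of 770 lower genes at -2.52 against -2.51 (100% of its size). With the length trend subtracted it was -2.48 (98.8%). Over all genes the median log2 fold change ran from -0.225 at the lowest to 0.499 at the highest GC content. By length it ran from 0.336 for the shortest to -0.279 for the longest transcripts. Subtracting trends this small had to leave most of the fall in genes chosen as lower. The subtractions therefore cannot tell whether GC content or length contributed to the falls. The deposited standard errors of the 280 lower genes with a mean count of at least 1000 were 1.43 times those of uncalled genes matched on mean count (95% bootstrap interval 1.39 to 1.48). Excess counts in a subset of pre-treatment libraries would give such a ratio, but so would a fall in only some tumours or tissue that varies between tumours, so without values per library these stay open, and a biological fall after treatment is untested.

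Neutrophil markers were higher after treatment, with all 17 positive and 0 of them in another list, although S100A8 (1.23), S100A9 (1.48) and CSF3R (1.56) in the authors' deposited table did not pass and tumour cells also express some members. A lower share of tumour or stromal cells would raise markers of all other cell types alike. The neutrophil median was 2.55 against 0.71, 1.15 and 0.44 for T cell, B cell and macrophage markers. Endothelial markers (0.22) belong to the stroma and need not rise under it. The largest adjusted p against these 4 lists was 0.0001 in permutation tests over genes, which are not independent, so that this p is too small. The medians argue against a lower share as the whole cause, but it could still be part of it. A scaling fault by the authors, alike for all genes or changing with mean count, would move other genes of like count as far, and the 95% range of medians of random matched lists ended at 0.48, against 2.55 for the neutrophil list. Whole blood in the biopsies cannot be told apart, because HBA1 (-1.43) and HBA2 (1.40) in the authors' deposited table are near-identical and can trade reads, their median with HBB was 0.08 (SD 1.42), and the 95% interval of HBB alone, -1.20 to 1.36, includes 50% of the neutrophil median (1.28). Another hypothesis that remains is that more granulocytes were in the tumours sampled after treatment, which may follow from the drug, from tissue handling or from differences between the patients sampled, and these were not tested.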
